A study of Danio rerio with 70 samples.

How the data were processed

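Stranded polyadenylated RNA libraries of 70 zebrafish samples were analysed from tables of raw read counts per Ensembl gene, deposited by the authors as counts. The tables hold 35117 genes, of which 27000 have a symbol in the reference list used, and genes without an informative symbol were tested but not named. STAR and the assembly GRCz10 are named per the submitters' processing notes, with no version, annotation release or strand setting given. Values were checked to be whole numbers with a different total in each column. The tables of the Frazer laboratory also hold summary rows of unmapped, multimapped and unassigned reads, which took 17.9% to 52.6% (median 36.7%) of all counts in their 46 samples and were left out. A further 9 columns match no labelled sample and were not analysed here. Reads counted to genes were 23730828 to 41393446 per sample in the Speleman laboratory and 8676867 to 56471528 in the Frazer laboratory. Samples were placed in 13 groups by the labels before the data were examined, as were the comparisons, their tests, the gene lists, the rule for naming genes and a first set of alternatives. Nothing says which samples came from separate animals beyond the tumour names of the transplants, so p-values measure only the spread between these samples. Over 201 pairs of replicates, Spearman rho across genes, which are not independent replicates, was 0.477 to 0.991, and the counts of each pair differed by more than counting error, with a smallest median chi-square of 2.85.

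Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with a minimum count of 10 and a minimum total count of 15, robust quasi-likelihood fits and F-tests, Benjamini-Hochberg adjustment and a threshold of 0.05 on adjusted p. Log2 fold changes are given with the SE that the F-test implies, and the values of groups in CPM (reads against library totals scaled by TMM factors, which ranged from 0.380 to 1.69) with SD. Group values in a comparison use the factors of its own fit, and values of single libraries and in figures those of all 70 libraries. The 6 primary TLX1 tumours and 6 thymi were fitted together, the mean of both tumour genotypes was set against thymus, and the heterozygous tumours were set against the others in the same fit. Transplant libraries were summed per tumour of origin and paired with that tumour in the model. Tumours of the hulk, otg and shrek lines were tested with all Frazer groups in 1 fit, and preleukemic samples with the healthy ones in a fit of 17 samples. The difference of models was the change of TLX1 tumours from thymi less the mean change of hulk, otg and shrek tumours from sorted thymocytes. A fold against a group with 0 reads was computed against a floor of 3 reads over that group and is given as at least that fold, and genes with 1 to 3 reads in a group are given by their reads and levels.

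Gene lists (22 pathways and gene families and 14 sets of cell type markers, 1090 names, 56 of them matching no gene) were tested with camera in limma 3.58.1 on voom weights at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with a correlation estimated for each list. Over the 14 comparisons with a direction, the 3 contrasts between lines aside, 218 of 504 list tests passed with the preset correlation and 1 with the estimated one. Of 36 lists each, 19 (otg less hulk), 18 (shrek less hulk) and 15 (shrek less otg) passed with the preset and 0 with the estimated one, so the list results otherwise rest on the preset. The pathway lists covered T-cell identity, T-cell receptor (TCR) rearrangement, T-ALL oncogenes, tumour suppressors, Notch, JAK-STAT and PI3K, BCL2, p53, PHF6-associated factors, ribosomes and their biogenesis, mitochondrial ribosomes, oxidative phosphorylation, proteasome, glycolysis, cholesterol synthesis, S phase, mitosis, immediate early, interferon, antigen presentation and egress genes. The marker lists covered B, cytotoxic, neutrophil, macrophage, erythroid, thrombocyte, progenitor, endothelial, fibroblast, thymic epithelial, skin, muscle, kidney and liver cells. Genes were named from those passing the test with an absolute log2 fold change of at least 1, at least 8 CPM in the higher group, at least 80% of samples beyond the reference group's extreme and an informative symbol (up to 10 each way), from described lists (up to 4 with the smallest adjusted p, or up to 3 with the highest mean where none changed) and from a panel of 30 gene IDs, and some genes so chosen are not reported here. Genes named for the overlap of models, and the germ-cell genes DDX4, DMC1 and PIWIL1 as a group, were chosen after their values were seen. Symbols are those of the reference list, in which zebrafish paralogues can share a human symbol, and reads shared between paralogues were not resolved.

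The first alternatives were DESeq2 size factors, no filter beyond 1 read, the DESeq2 test (1.42.0), limma voom with sample weights, only the compared groups in a fit, a block on replicate numbers, leaving out each sample of groups of 2 to 5, and other treatments of transplants. Added after the data were seen were library size alone, fits without mitochondrial genes, without the 3 libraries above 20% mitochondrial reads, without the 3 libraries with fewer than 12000 genes at 10 reads (hulk tumour 7, otg tumours 5 and 8), without marker genes of other cell types, and without the 2 transplant libraries passed on from another. Whether equal replicate numbers pair samples was checked by correlating deviations from group means. Only preleukemic hMYC and healthy samples met the rule, with correlations of 0.115 to 0.164 over 3 pairs. Each test was run on simulated counts with known changes in 100 genes each at 2-fold and 4-fold. It recovered, at 2-fold and 4-fold, 13 and 69 (TLX1 tumours against thymi), 0 and 24 (phf6 heterozygous against other TLX1 tumours), 15 and 70 (transplants against primary tumours), 7 and 53 (hulk tumours), 6 and 59 (otg tumours), 5 and 53 (shrek tumours), 14 and 81 (the 3 lines jointly), 6 and 57 (preleukemic hulk), 8 and 60 (preleukemic otg), 6 and 43 (preleukemic shrek), 3 and 58 (preleukemic hMYC), 2 and 37 (hulk tumours against preleukemic), 2 and 36 (otg tumours against preleukemic), 1 and 32 (shrek tumours against preleukemic), 1 and 18 (the difference of models), with at most 4 false calls among unchanged genes. Correlations and permutations used Python 3.11.15 with scipy 1.17.1, and plots matplotlib 3.10.9.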

Results

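Polyadenylated RNA was sequenced from healthy thymus, preleukemic thymocytes and T-cell acute lymphoblastic leukaemia (T-ALL) of zebrafish, in 70 libraries of 13 groups from a pair of laboratories. The Speleman laboratory gave 6 dissected thymi of rag2:GFP fish, 2 primary T-ALLs of fish that express human TLX1 from the rag2 promoter and 4 primary TLX1 T-ALLs of phf6 heterozygous fish. From immunodeficient recipients of 4 of those tumours came 12 transplant libraries, 6 of each genotype, 2 of them by name passed on from transplant 2-2 of TLX1 tumour 2. The Frazer laboratory gave sorted GFP-positive cells of lck:GFP fish, which were 5 healthy thymocyte samples and T-ALLs of the mutant lines hulk (9), otg (10) and shrek (10). It also gave preleukemic thymocytes of hulk (3), otg (4), shrek (2) and human MYC transgenic fish (hMYC, 3). Reads counted to genes ranged from 26285736 to 32977057 per library in the dissected thymi, 38558162 to 39433264 in TLX1 tumours and 28526934 to 34544499 in phf6 heterozygous TLX1 tumours. Their transplants had 31976625 to 41393446 and 23730828 to 37849055. Sorted healthy thymocytes had 13259934 to 15437586 reads, and hulk, otg and shrek tumours 10899692 to 16260759, 11221370 to 16330010 and 14247623 to 19537019. Preleukemic hulk, otg, shrek and hMYC samples had 8676867 to 11875689, 12611959 to 17438868, 47598816 to 56471528 and 17640353 to 18966569.

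PHF6 (ENSDARG00000004046), a chromatin-associated tumour suppressor of human T-ALL and the gene altered in the heterozygous fish, was examined first in every library of the TLX1 model. It was measured at 17.3 to 19.9 CPM in the 6 thymi. The 4 heterozygous primary tumours had 13.2, 9.15, 10.7 and 10.5 CPM. Of the TLX1 tumours whose labels name no phf6 allele, tumour 1 had 19.9 CPM and tumour 2 had 6.42 CPM, the latter below all 4 heterozygous tumours on the TMM scale used for CPM here. By library size alone that order did not hold: tumour 2 was at 4.07 CPM, tumour 1 at 14.7, the heterozygous tumours at 11.96, 3.88, 7.43 and 6.00, and thymi at 25.2 to 33.7. Transplant libraries ranged over 15.07 to 19.8 CPM for tumour 1, 6.22 to 8.14 CPM for tumour 2, and 12.1 to 14.9 and 10.9 to 13.1 CPM for heterozygous tumours 1 and 2. The difference of the genotypes in primary tumours did not pass the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (log2 fold change -0.33 ± 0.34 (SE), edgeR adjusted p = 0.701). The zebrafish TLX1 gene, which is not the human transgene, had at most 2 reads in any library of the TLX1 model.

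**Figure D1:**
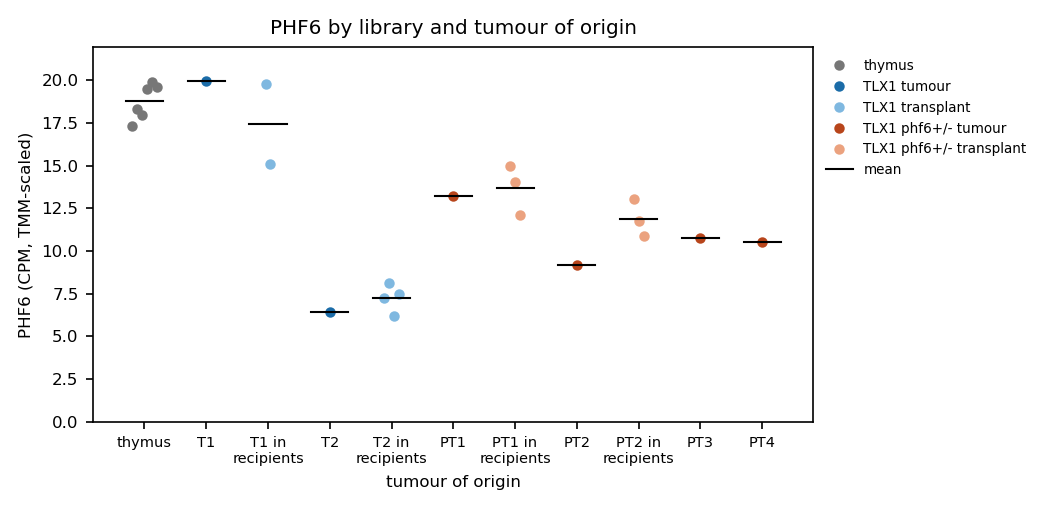
CPM of PHF6 (vertical axis, linear from 0) in each library of the TLX1 model, grouped by genotype and tumour of origin; points are libraries and bars are group means. TLX1 tumour 2 at 6.42 CPM and its transplants at 6.22 to 8.14 CPM lay below the heterozygous primary tumours on this TMM scale.

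Which transcripts separate TLX1-driven leukaemia from normal thymus was asked with the 6 primary tumours and the 6 dissected thymi. The tumours were rich in transcripts of the protein synthesis machinery and poor in those of muscle, skin and thymic stroma. Cytosolic ribosomal protein genes took 42.6% ± 0.633 (SD, n = 2) of reads in TLX1 tumours and 43.7% ± 6.51 (SD, n = 4) in phf6 heterozygous ones, against 19.3% ± 2.26 (SD, n = 6) in thymi. RAG1, a recombinase of antigen receptor genes, rose from 3250.0 ± 405 CPM (SD, n = 6) to 12100.0 ± 6693 CPM (SD, n = 6), with edgeR adjusted p = 0.000694. The receptors NOTCH1 (ENSDARG00000052094), with log2 fold change -3.90 ± 0.43 (SE), edgeR adjusted p = 1.5e-05, and NOTCH3, with -4.46 ± 0.52, edgeR adjusted p = 2.28e-05, fell. MYC ENSDARG00000045695 rose, with 3.36 ± 0.98, edgeR adjusted p = 0.0104, while its paralogue ENSDARG00000007241 did not pass, with 3.01 ± 1.32, edgeR adjusted p = 0.0692. The former rose in 4 of 6 tumours but was at 3.81 and 7.24 CPM in TLX1 tumour 2 and heterozygous tumour 2, below the 33.1 to 45.0 CPM of thymi.

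In all, 12443 of 22224 tested genes changed, 4493 upwards and 7950 downwards, and 2142 and 7554 of them by at least 2-fold. Scaled by library size alone, 606 genes were higher and 16318 lower, and the median log2 fold change of all genes moved from -0.19 to -1.45, so the directions given are relative to the bulk of genes. Among genes meeting the fixed naming rule, the largest rise was that of SIM1 (ENSDARG00000023316), a transcription factor of hypothalamic development, with log2 fold change 7.30 ± 1.18 (SE), edgeR adjusted p = 0.000222. Next came PLAC8L1, with 6.96 ± 0.66, edgeR adjusted p = 5.15e-06, and the potassium channel gene KCNH5, with 6.77 ± 0.53, edgeR adjusted p = 1.48e-06. CELA1, a pancreatic elastase, the hormone gene STC1, syndig1l, the uncoupling protein gene UCP1, the synaptic vesicle gene SYNPR, ADAMTS18 and MFSD4A rose by 6.52, 6.40, 6.15, 5.91, 5.76, 5.53 and 5.46 on the log2 scale. Each of these 10 genes was above all 6 thymi in at least 5 of 6 tumours. Several transcripts of thymus samples had 0 reads in all 6 tumours, among them the keratin gene krt95 (at least 684-fold lower) and the parvalbumin gene pvalb5 (at least 445-fold). The collagen gene col9a3, the cone opsin gene opn1lw2 and GNG11 were likewise at least 418-fold, at least 408-fold and at least 365-fold lower. The thymoproteasome gene PSMB11 and the muscle myosin gene myhz2 had 1 read and 1 read over the 6 tumours, against 31.0 ± 4.18 CPM (SD, n = 6) and 34.3 ± 7.93 CPM (SD, n = 6) in thymi. Further, ctsll fell by 11.45 and cpeb1a by 11.30 on the log2 scale.

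Among the gene lists, 76 of 77 cytosolic ribosomal protein genes rose and 1 fell (76 and 1 adjusted over the list alone), with RPL35 at 2.32 ± 0.17 and rps3 at 2.93 ± 0.21 on the log2 scale. The camera gene set test gave adjusted p = 1.39e-40 for this list, and adjusted p = 0.409 with an estimated correlation between its genes. Of ribosome biogenesis, 48 of 53 genes rose (49 adjusted over the list alone), including DDX21 (2.73) and BOP1 (2.70). By library size alone 2 rose and 14 fell. Of mitochondrial ribosomal proteins, 58 of 72 genes rose (60 adjusted over the list alone), and 0 rose and 47 fell scaled by library size alone. Of oxidative phosphorylation, 43 of 86 genes rose and 2 fell (42 and 2 adjusted over the list alone), and 0 rose and 69 fell on that scale. These 3 lists had camera adjusted p = 1.61e-18, 6.49e-15 and 7.24e-10, and adjusted p = 0.275, 0.65 and 0.671 with an estimated correlation. Similarly, 11 of 21 genes of PHF6-associated chromatin and rRNA factors rose and 1 fell (11 and 2 adjusted over the list alone). The camera test gave adjusted p = 0.00244, and adjusted p = 0.671 with an estimated correlation. Of this list, 0 rose and 13 fell by library size alone. Cholesterol synthesis moved down, as 1 of 23 genes rose and 14 fell (3 and 14 adjusted over the list alone). Here camera gave adjusted p = 0.0311, and adjusted p = 0.65 with an estimated correlation. Its lower members included HSD17B7 (-4.34), the LDL receptor gene ldlra (-5.50) and SQLE (-5.06), an enzyme of sterol synthesis.

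Of the Notch pathway, 1 of 19 genes rose and 11 fell (1 and 11 adjusted over the list alone), including the target gene HEY1 (-5.56). Of lymphocyte egress and homing, 2 of 15 genes rose and 10 fell (2 and 10 adjusted over the list alone), including the chemokine receptors CXCR4 ENSDARG00000057633 (-4.41) and CCR7 (-3.04). Neither list passed. Testing by camera gave adjusted p = 0.0731 and 0.115, and adjusted p = 0.65 and 0.727 with an estimated correlation. T-cell identity genes went both ways, as 6 of 30 genes rose and 14 fell (6 and 14 adjusted over the list alone), with txk at -4.12 and cd4-2.2 at -2.95. A camera test gave adjusted p = 0.768, and adjusted p = 0.93 with an estimated correlation. Marker genes of other tissues were lower in tumours: 29 of 29 skeletal muscle genes fell (29 adjusted over the list alone), among them TNNI2 (-8.59) and MYL1 (-5.78). Likewise 19 of 21 thymic epithelium genes fell (19 adjusted over the list alone), among them the thymopoietic cytokine gene il7 (-5.43). Also, 19 of 21 skin and surface epithelium genes fell (19 adjusted over the list alone), among them pvalb8 (-7.40). Further, 1 of 29 fibroblast and extracellular matrix genes rose and 21 fell (1 and 22 adjusted over the list alone), among them SPARC (-5.87) and POSTN ENSDARG00000104267 (-4.63). These 4 lists had camera adjusted p = 1.37e-13, 6.54e-09, 6.18e-07 and 0.000215, and adjusted p = 0.231, 0.231, 0.625 and 0.727 with an estimated correlation. Skeletal muscle genes took 0.592% ± 0.106 (SD, n = 6) of reads in thymi and 0.00640% ± 0.00153 (SD, n = 4) in phf6 heterozygous tumours. Of neutrophil markers, 6 of 9 genes rose and 1 fell (6 and 1 adjusted over the list alone), among them npsn (3.4), lyz (4.23) and illr4 (4.79). By library size alone, 3 rose and 3 fell. Of liver genes, 10 of 17 genes rose and 1 fell (11 and 1 adjusted over the list alone), among them the fibrinogen gene fga (4.82). Both lists had camera adjusted p = 0.00191 and 0.0142, and adjusted p = 0.65 and 0.772 with an estimated correlation. Liver genes took 0.461% of reads in heterozygous tumour 2, but 0.00550% to 0.0668% in the other tumours and 0.0468% to 0.133% in thymi.

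Whether a phf6 allele changes the TLX1 leukaemia was asked by comparing the 4 primary tumours labelled phf6 heterozygous with the 2 other primary TLX1 tumours, of which tumour 2 was as low in PHF6 RNA as heterozygous ones. The adhesion receptor gene CXADR ENSDARG00000043658 rose, with log2 fold change 5.43 ± 0.72 (SE), edgeR adjusted p = 0.0325, from 0.435 ± 0.186 CPM (SD, n = 2) to 19.1 ± 10.8 CPM (SD, n = 4). The ferritin-like gene fthl28 rose by 3.08 on the log2 scale, with edgeR adjusted p = 0.0351. RNF14, with -3.47 ± 0.51, edgeR adjusted p = 0.0351, and MACROD2, with -1.62 ± 0.23, edgeR adjusted p = 0.0351, fell. RNF14 had 42.1 ± 45.3 CPM (SD, n = 2) in the other TLX1 tumours, and without TLX1 tumour 1 its change was -1.41, edgeR adjusted p = 0.0988. In all, 9 of 22224 genes passed, 5 higher and 4 lower (10 and 3 with DESeq2 size factors, 5 and 6 by library size alone). There were 3009 genes with an unadjusted p under 0.05. The count was 70, 28 and 31 without heterozygous tumours 1, 2 and 3, and 155 and 106 without TLX1 tumours 1 and 2. It was 707 by the DESeq2 test and 1 by limma voom, so it rests on the tumours and tool used. Of glycolysis, 0 of 32 genes passed the edgeR test over all genes (3 higher and 11 lower adjusted over the list alone). There were 5 higher and 12 lower at an unadjusted p under 0.05, 1 higher and 2 lower by DESeq2 and 0 higher and 0 lower by limma voom. Of erythroid markers, 0 of 21 genes passed the edgeR test over all genes (7 higher and 0 lower adjusted over the list alone). There were 11 higher and 0 lower at an unadjusted p under 0.05, 6 higher and 0 lower by DESeq2 and 0 higher and 0 lower by limma voom. These lists had camera adjusted p = 8.81e-05 and 1.33e-08, and adjusted p = 0.475 for each with an estimated correlation, and leaned lower and higher in heterozygous tumours. Of skeletal muscle markers, 0 of 29 genes passed the edgeR test over all genes (12 higher and 0 lower adjusted over the list alone). There were 15 higher and 0 lower at an unadjusted p under 0.05, 9 higher and 0 lower by DESeq2 and 0 higher and 0 lower by limma voom. Camera gave adjusted p = 9.78e-08, and adjusted p = 0.475 with an estimated correlation.

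What transplantation into immunodeficient fish changes was asked with 4 primary tumours and the summed reads of their transplants, paired by tumour of origin. The 2 passed-on libraries were summed with the others of their tumour, and without them 14 genes passed. Some neutrophil and B-cell transcripts fell. The immunoglobulin heavy chain gene ighm fell from 85.9 ± 66.7 CPM (SD, n = 4) to 1.38 ± 0.875 CPM (SD, n = 4), with edgeR adjusted p = 0.0354. The neutrophil genes mmp13a, with log2 fold change -3.05 ± 0.19 (SE), edgeR adjusted p = 0.0022, and lyz, with -2.62 ± 0.26, edgeR adjusted p = 0.0158, fell. So did illr4, with -2.57 ± 0.30, edgeR adjusted p = 0.0239, npsn, with -2.02 ± 0.26, edgeR adjusted p = 0.0354, and the pancreatic carboxypeptidase gene CPA1 (-2.03). In all, 19 of 15504 genes passed, 1 higher and 18 lower. Scaling by library size alone gave 154 higher and 147 lower and moved the median of all genes from 0.02 to 0.22. Without tumour 2 the count was 52, without heterozygous tumours 1 and 2 it was 36 and 7, by the DESeq2 test 666, and with each transplant library entered on its own 336. Of neutrophil markers, 4 of 9 genes fell (7 adjusted over the list alone). Of B-cell markers, 2 of 15 genes fell (7 adjusted over the list alone). The camera test gave adjusted p = 5.68e-12 and 1.1e-09, and adjusted p = 0.175 and 0.363 with an estimated correlation. Of mitosis, 0 of 35 genes passed the edgeR test over all genes (27 higher and 0 lower adjusted over the list alone). There were 29 higher and 0 lower at an unadjusted p under 0.05, 19 higher and 0 lower by DESeq2 and 0 higher and 0 lower by limma voom. Of erythroid markers, 0 of 18 genes passed the edgeR test over all genes (0 higher and 12 lower adjusted over the list alone). There were 0 higher and 14 lower at an unadjusted p under 0.05, 0 higher and 12 lower by DESeq2 and 0 higher and 0 lower by limma voom. These lists, of which mitosis leaned higher and erythroid markers lower, had camera adjusted p = 4.16e-22 and 9.38e-14, and adjusted p = 0.426 and 0.363 with an estimated correlation. Scaled by library size alone, 22 mitosis genes rose and 8 erythroid genes fell.

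How leukaemias of the mutant lines hulk, otg and shrek differ from healthy thymocytes was asked with sorted GFP-positive cells. The healthy samples came in a table of their own, so a difference between tables and one between groups cannot be told apart. Germ-cell transcripts were high in some hulk tumours. The RNA helicase gene DDX4 (ENSDARG00000014373) rose from 0.0853 ± 0.0734 CPM (SD, n = 5) to 37.8 ± 45.0 CPM (SD, n = 9), with log2 fold change 8.72 ± 2.16 (SE), edgeR adjusted p = 0.00895. PIWIL1, a partner of germline small RNAs, rose from 0.186 ± 0.138 CPM (SD, n = 5) to 38.2 ± 48.7 CPM (SD, n = 9), with 7.64 ± 2.02, edgeR adjusted p = 0.0124. DDX4 was at 0.228 (2 reads), 1.42 and 2.64 CPM in hulk tumours 7, 5 and 9 and up to 113 CPM in tumour 4. In otg tumours 6 and 7 and shrek tumour 001 it was at 12.04, 6.35 and 11.8 CPM, and PIWIL1 at 24.3, 14.0 and 16.8 CPM. The Notch pathway genes DTX1 (-2.64) and RBPJ ENSDARG00000052091 (-1.87) and the T-cell transcription factor genes TCF7 (-1.99) and SATB1 (-3.14) fell.

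In all, 2983 of 21831 genes changed between hulk tumours and healthy thymocytes, 1850 higher and 1133 lower. Library size alone gave 939 higher and 1101 lower and moved the median of all genes from 0.10 to -0.24. The count was 1428, 1384, 1416 and 1777 without healthy samples 1, 2, 4 and 5, and 1948 without the 3 libraries above 20% mitochondrial reads, which were hulk tumours 1 and 2 and healthy sample 3. An RNA helicase gene listed as ddx19a, a symbol paralogues may share, and the RNA-binding protein gene ELAVL2 had 0 reads in healthy samples. They were at least 458-fold and at least 263-fold higher. The genes aste1a, znf541, pld6, DMC1, a meiotic recombinase, and DNAJB13 had 1, 1, 1, 2 and 2 reads over the healthy samples. Their tumour means were 27.0 ± 14.3, 8.65 ± 7.0, 8.44 ± 10.4, 9.59 ± 11.7 and 8.54 ± 9.68 CPM (SD, n = 9). The inflammasome-type gene nlrp3l2, with -6.03 ± 0.89, edgeR adjusted p = 3.41e-05, and the TNF receptor gene tnfrsfa, with -5.32 ± 0.87, edgeR adjusted p = 0.00015, fell. So did SLC10A1, CHST15, myo1hb, the guanylate-binding protein gene gbp4, ifi44a5, LOXL4, the Notch target HES1 and the calcium channel gene TRPV6 (-4.87, -4.59, -4.54, -4.54, -4.5, -4.42, -4.08 and -4.04). Each of these 10 was below all healthy samples in at least 8 of 9 tumours. Without healthy sample 3 the change of HES1 was -1.32, edgeR adjusted p = 0.241.

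By list, 20 of 47 proteasome genes rose and 2 fell (35 and 2 adjusted over the list alone), among them PSMC1 (1.3) and PSMD13 (1.21). Downwards, 7 of 30 T-cell identity genes fell (7 adjusted over the list alone) and 5 of 16 Notch pathway genes fell (6 adjusted over the list alone). Also, 5 of 15 lymphocyte egress and homing genes fell (7 adjusted over the list alone), including CXCR4 ENSDARG00000057633 (-2.97). These 4 lists had camera adjusted p = 1.27e-08, 0.00227, 0.00197 and 0.00227, and adjusted p = 0.525, 0.456, 0.456 and 0.456 with an estimated correlation. Of JAK-STAT and PI3K signalling, 3 of 29 genes fell (3 adjusted over the list alone), namely STAT3 (-1.40), stat5a (-1.81) and il2rga (-1.44). Of antigen presentation, 3 of 21 genes rose (5 adjusted over the list alone), namely mhc1zca (3.84), PSMB9 (1.45) and PSMB8 (1.21). Here camera gave adjusted p = 0.0174 and 0.129, and adjusted p = 0.525 and 0.817 with an estimated correlation. Mitochondrial transcripts took 61.4% of reads in hulk tumour 2 and 25% in hulk tumour 1.

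**Figure D2:**
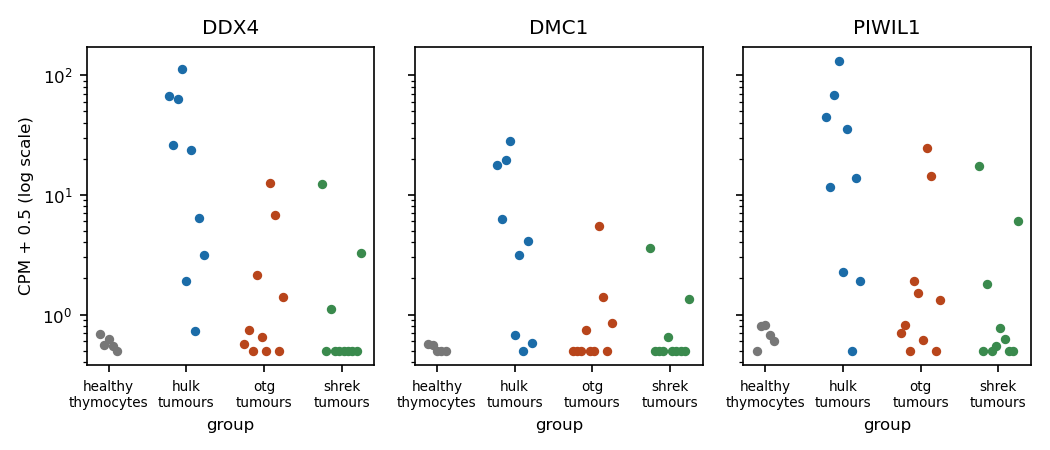
CPM of DDX4, DMC1 and PIWIL1 (vertical axis, log scale, after adding 0.5 CPM) in each hulk, otg and shrek tumour and each healthy thymocyte sample; points are libraries. The mean of DDX4 on this scale was 33.4 CPM in hulk tumours and 0.0832 CPM in healthy samples.

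Leukaemias of the otg line were rich in transcripts of ribosomes and mitochondria. Cytosolic ribosomal protein genes took 24.6% ± 10.7 (SD, n = 10) of reads in otg tumours and 12.1% ± 2.96 (SD, n = 5) in healthy thymocytes. The homeobox gene LMX1B (ENSDARG00000068365) rose from 0.152 ± 0.0653 CPM (SD, n = 5) to 33.9 ± 75.4 CPM (SD, n = 10), with log2 fold change 7.75 ± 1.74 (SE), edgeR adjusted p = 0.00132. The integrin gene ITGA6 rose with 7.17 ± 1.29, edgeR adjusted p = 0.000166. The haematopoietic regulator LMO2, with -2.32 ± 0.60, edgeR adjusted p = 0.00431, and the survival gene bcl2a, with -2.47 ± 0.59, edgeR adjusted p = 0.00223, fell. The B-cell receptor gene cd79a fell with -1.89 ± 0.51, edgeR adjusted p = 0.00567. In all, 6105 of 21831 genes changed, 2800 higher and 3305 lower. Scaling by library size alone gave 742 higher and 4902 lower and moved the median of all genes from -0.04 to -0.58. With only these groups in the fit the total was 1769. The transcription factor gene SIM1 had 2 reads in healthy samples and 39.5 ± 62.1 CPM (SD, n = 10) in tumours. Further rises were those of znf1156, trim35-14, the calcium channel subunit gene CACNG2, chtopb and GGACT ENSDARG00000038248 (8.45, 7.79, 7.33, 7.10 and 6.94). The transcription factor gene OSR2, with -6.86 ± 0.87, edgeR adjusted p = 7.9e-07, the protease gene BACE2, prune2, NSG2, CHST15, ANKS1B, herc56.3, ITGB6, casp23 and LOXL4 fell, the last 9 with log2 fold changes of -6.70 to -5.59.

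By list, 60 of 77 cytosolic ribosomal protein genes rose (66 higher and 1 lower adjusted over the list alone), such as RPL4 (2.09) and RPL3 (2.37). Also, 28 of 53 ribosome biogenesis genes rose (29 adjusted over the list alone), such as WDR12 (1.74). Of 72 mitochondrial ribosomal protein genes, 59 rose (65 adjusted over the list alone). Of 47 proteasome genes, 35 rose and 2 fell (37 and 2 adjusted over the list alone). Likewise 57 of 84 oxidative phosphorylation genes rose (65 adjusted over the list alone). These 5 lists had camera adjusted p = 1.05e-21, 1.26e-09, 4.47e-20, 8.61e-13 and 1.7e-16, and adjusted p = 0.344 for each with an estimated correlation. Lower were 7 of 23 cholesterol synthesis genes (7 adjusted over the list alone), such as insig1 (-1.90) and SQLE (-3.69). For B cells, 1 of 19 genes rose and 9 fell (1 and 9 adjusted over the list alone), among them the kinase gene SYK (-4.23) and PAX5 (-4.97). For fibroblasts and matrix, 1 of 29 genes rose and 18 fell (1 and 21 adjusted over the list alone), among them COL1A2 (-4.89). Those lists had camera adjusted p = 0.00568, 1.85e-05 and 6.45e-05, and adjusted p = 0.344 for each with an estimated correlation.

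Leukaemias of the shrek line were poor in transcripts of cytotoxic and B cells and of the immediate early response. The recombinase genes RAG1, with log2 fold change 2.56 ± 0.88 (SE), edgeR adjusted p = 0.0232, and RAG2, with 1.48 ± 0.50, edgeR adjusted p = 0.0223, rose. RAG1 went from 1199 ± 1160.0 CPM (SD, n = 5) to 7074 ± 4665 CPM (SD, n = 10). The collagen genes col18a1a, with 7.63 ± 1.73, edgeR adjusted p = 0.000854, and col5a3a, with 8.49 ± 1.90, edgeR adjusted p = 0.000772, rose. The T-box gene EOMES ENSDARG00000104243 (-5.51) and the kinase gene SYK (-7.05) fell. In all, 6593 of 21831 genes changed, 1863 higher and 4730 lower. The split was 1159 and 5314 with DESeq2 size factors and 761 and 5023 by library size alone, which moved the median of all genes from -0.02 to -0.21 and -0.27. SIM1 and the synapse gene nlgn2b had 2 reads and 2 reads in healthy samples and 47.4 ± 76.2 CPM (SD, n = 10) and 9.56 ± 11.2 CPM (SD, n = 10) in tumours. Moreover, opn4xb, NXPH1, VSTM2A, AMDHD1, the homeobox gene PHOX2A and KIRREL1 rose by 8.02, 7.91, 7.85, 7.36, 7.29 and 7.18 on the log2 scale. The transcriptional co-repressor gene NAB1, with -9.38 ± 1.24, edgeR adjusted p = 8.75e-07, the immune receptor genes nitr1i (-8.46) and nitr5 (-8.27) and mbpa (-8.48) fell. So did RERGL, OSR2, myo1hb and rgs5b (-8.37, -8.36, -8.16 and -8.09), and each of the 8 was below all healthy samples in at least 9 of 10 tumours.

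Of immediate early and heat shock genes, 19 of 29 genes fell (21 adjusted over the list alone), among them ATF3 (-3.77), FOSL2 (-5.0) and DUSP1 (-2.78). Of markers of other blood cells, 13 of 16 NK-like and cytotoxic genes fell (14 adjusted over the list alone) and 12 of 19 B-cell genes fell (13 adjusted over the list alone), including cd37 (-6.23). Also, 13 of 28 macrophage and dendritic genes fell (16 adjusted over the list alone), including csf1rb (-5.33) and MPEG1 (-2.92). In addition, 8 of 16 haematopoietic progenitor genes fell (1 higher and 8 lower adjusted over the list alone), including GATA2 (-4.11). These 5 lists had camera adjusted p = 2.49e-06, 2.37e-06, 6.37e-07, 1.18e-05 and 0.00095, and adjusted p = 0.22, 0.22, 0.22, 0.281 and 0.22 with an estimated correlation. Among BCL2 family genes, 8 of 20 genes fell (10 adjusted over the list alone), such as the pro-apoptotic pmaip1 (-3.04) and the pro-survival mcl1a (-1.99). Among egress and homing genes 9 of 15 genes fell (11 adjusted over the list alone), such as CXCR4 ENSDARG00000057633 (-5.08). Upwards, 5 of 15 genes of TCR rearrangement and thymocyte immaturity rose (5 adjusted over the list alone), such as LIG4 (1.55). These 3 lists had camera adjusted p = 0.002, 4.88e-05 and 0.0155, and adjusted p = 0.22, 0.22 and 0.306 with an estimated correlation.

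How the leukaemias of the lines differ from each other was asked by pairwise contrasts of the 29 tumours. Relative to hulk tumours, GGACT ENSDARG00000038248 (log2 fold change 7.29 ± 1.24 (SE), edgeR adjusted p = 0.00011) and nlrp3l2 (5.96 ± 0.84, edgeR adjusted p = 7.19e-06) were higher in otg tumours. The cadherin gene cdh29 (-10.67 ± 1.35, edgeR adjusted p = 8.99e-07), rps11l and NPTN (-7.10 and -7.06) were lower there. In shrek relative to hulk, the collagen genes col5a3a (7.75 ± 1.40, edgeR adjusted p = 5.62e-05) and col16a1 (7.29) and the calcium channel gene cacna1aa (5.83) were higher. RAG1 rose by 2.32 on the log2 scale. NPTN (-8.52) and NAB1 (-7.57) were lower, and aste1a, with 0 reads in all 10 shrek tumours, was at least 1762-fold lower. In shrek relative to otg, cdh29 (10.58 ± 1.34, edgeR adjusted p = 7.25e-07), BACE2 (6.79), AMDHD1 (6.00) and HAO2 (5.84) were higher. The lipid phosphatase gene PLPP3 (-6.26), znf1156 (-6.02) and the co-stimulatory receptor gene cd28 (-4.09) were lower. Over the 3 lines, 11730 genes differed by the joint test. The pairwise contrasts passed for 6196 genes in otg against hulk (2029 higher, 4167 lower), 10192 in shrek against hulk (3336 higher, 6856 lower) and 3932 in shrek against otg (980 higher, 2952 lower). By library size alone the contrast of otg against hulk gave 799 higher and 5116 lower and that of shrek against otg 961 and 1083. The medians of all genes moved from -0.06 to -0.35 and from -0.16 to 0.18. Among T-ALL tumour suppressors and chromatin regulators, 13 of 32 genes rose and 2 fell (13 and 2 adjusted over the list alone) in shrek against hulk, such as the histone demethylase genes kdm6bb (2.79) and kdm6al (1.85) and the DNA methyltransferase gene DNMT3A (2.34). Testing by camera gave adjusted p = 0.000124, and adjusted p = 0.384 with an estimated correlation.

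Preleukemic thymocytes of each line were set against the 5 healthy samples, whose separate table again cannot be told apart from group. In preleukemic hulk thymocytes the ubiquitin-like interferon gene isg15 rose from 7.86 ± 7.28 CPM (SD, n = 5) to 489 ± 426 CPM (SD, n = 3), with log2 fold change 5.96 ± 0.89 (SE), edgeR adjusted p = 0.00187. RSAD2, an antiviral enzyme, and mxc rose by 5.18 and 3.19 on the log2 scale. Of the vitellogenins, yolk proteins made in the liver, vtg1 had 132 ± 197 CPM (SD, n = 3) against 0.176 ± 0.279 CPM (SD, n = 5), and vtg7 rose by 8.83 on the log2 scale. Sample 3 held 91.0% and 93.9% of the summed CPM of vtg1 and vtg7 in this group. The Src-family kinase gene lck, with -1.22 ± 0.32, edgeR adjusted p = 0.0417, and the terminal transferase gene dntt, with -3.75 ± 1.03, edgeR adjusted p = 0.0499, fell. So did gbp4, cacna1aa, gzma, a granzyme, and CHST15 (-5.95, -5.57, -3.79 and -3.46), while trim35-14 rose by 9.23 on the log2 scale. In all, 737 of 19531 genes changed, 437 higher and 300 lower. Library size alone gave 319 higher and 105 lower. The count was 4441, 267 and 203 without preleukemic samples 1, 2 and 3, and 2181 and 389 without healthy samples 3 and 4. It was 105 with only these groups in the fit and 1883 by the DESeq2 test. Of interferon response genes, 15 of 28 genes rose and 1 fell (20 and 1 adjusted over the list alone). Of T-ALL oncogenes, 5 of 18 genes fell (6 adjusted over the list alone), such as MEF2C (-2.0) and MYB (-1.56). A camera test gave adjusted p = 1.01e-08 and 0.0489, and adjusted p = 0.452 and 0.569 with an estimated correlation.

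In preleukemic otg thymocytes, MYC ENSDARG00000045695 fell from 349 ± 186 CPM (SD, n = 5) to 126 ± 33.1 CPM (SD, n = 4), with log2 fold change -1.48 ± 0.39 (SE), edgeR adjusted p = 0.036. The potassium channel gene KCNJ13, with 7.89 ± 0.79, edgeR adjusted p = 2.38e-05, CACNG2, trim35-14, znf1156, NXPH1, GGACT ENSDARG00000038248, KLHL31 and the growth factor gene fgf9 rose, the last 7 with log2 fold changes of 6.14 to 7.85. The gene aste1a had 1 read in healthy samples and 12.9 ± 1.97 CPM (SD, n = 4). The elastase gene ela2l had 1 read over the 4 preleukemic samples against 57.6 ± 118 CPM (SD, n = 5), of which healthy sample 3 held 93.8%. Further, rps11l, BACE2, NSG2, CHST15, gucy2cb, the heat shock gene hsp70.1 and the chemokine receptor gene CCR6 fell (-7.24, -6.57, -6.18, -6.04, -5.97, -6.23 and -5.80). Without healthy sample 3 the change of hsp70.1 was -2.97, and without preleukemic sample 3 that of fgf9 was 3.45, edgeR adjusted p = 0.146. In all, 1041 genes changed, 342 higher and 699 lower. Leaving out preleukemic samples 1 to 4 in turn gave 413, 595, 398 and 372, leaving out healthy samples 1, 2 and 5 gave 499, 516 and 1851, and the DESeq2 test 2058. Lower were 5 of 18 B-cell genes (15 adjusted over the list alone) and 5 of 16 NK-like and cytotoxic genes (12 adjusted over the list alone), such as the perforin gene prf1.1 (-3.76). Also, 6 of 28 immediate early and heat shock genes fell (10 adjusted over the list alone). Camera gave adjusted p = 3.04e-05, 0.000183 and 0.000181, and adjusted p = 0.696 for each with an estimated correlation.

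Preleukemic shrek thymocytes (2 samples) were rich in transcripts of proliferation and of mitochondria. The ribonucleotide reductase gene RRM2 rose from 158 ± 40.7 CPM (SD, n = 5) to 1556 ± 92.8 CPM (SD, n = 2), with log2 fold change 3.30 ± 0.25 (SE), edgeR adjusted p = 3.1e-06. The replication clamp gene PCNA rose with 1.40 ± 0.27, edgeR adjusted p = 0.00126. AURKB, CDK1, RAG2 and cd8a rose by 2.55, 2.22, 1.60 and 1.21. PHF6 rose by 0.70, but by library size had 19.7 and 24.6 CPM (healthy 16.4 to 23.6). NXPH1, trim35-14, TMEFF2, FAM151B, GALK2, DHRS3, DNAH7 and COL12A1 rose by 7.31, 6.75, 5.02, 4.52, 4.5, 3.95, 3.92 and 3.91 on the log2 scale, and ifi30b, with 0 reads in healthy samples, was at least 199.8-fold higher. The calcium-binding protein gene S100B had 0 reads in preleukemic shrek and was at least 266-fold lower, and mbpa, CHST12, tnfrsf9b, bmf2, AGO3, ANO5 and the interleukin receptor gene il2rb fell (-8.37, -7.99, -7.43, -7.42, -7.05, -6.73 and -6.72). In all, 7424 genes changed, 3388 higher and 4036 lower. Scaling by library size alone gave 1402 higher and 5365 lower and moved the median of all genes from -0.27 to -0.82 (-0.42 with DESeq2 size factors). The count fell when either sample was left out, and these libraries were deeper than healthy ones. By list, 26 of 42 S phase genes rose and 2 fell (30 and 2 adjusted over the list alone) and 23 of 34 mitosis genes rose (25 adjusted over the list alone). Likewise 74 of 84 oxidative phosphorylation genes rose (78 adjusted over the list alone). The camera test gave adjusted p = 2.62e-09, 8.51e-10 and 4.23e-20, and adjusted p = 0.75 for each with an estimated correlation.

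In preleukemic thymocytes of hMYC fish, the MHC class II genes mhc2dgb and mhc2dga and the gene nlrc11 had 0 reads in all 3 samples and were at least 1176-fold, at least 588-fold and at least 1165-fold lower than in healthy thymocytes. Zebrafish MYC ENSDARG00000045695, with log2 fold change -2.05 ± 0.45 (SE), edgeR adjusted p = 0.00583, and MYC ENSDARG00000007241, with -1.29 ± 0.45, edgeR adjusted p = 0.0488, fell. Upwards, RAG1, with 2.97 ± 0.72, edgeR adjusted p = 0.0106, cd4-1 (1.3) and cd8a (1.12) rose. The glycosyltransferase gene GALNT17, with 9.74 ± 0.88, edgeR adjusted p = 4.57e-06, and the melanocyte regulator MITF, with 9.30 ± 0.80, edgeR adjusted p = 4.38e-06, rose. So did KCNJ13, setd1bb, col5a3a, btbd16 and pgbd4, by 8.87, 7.65, 7.29, 7.14 and 7.01 on the log2 scale. The genes mbpa, CPA1, a carboxypeptidase, BACE2 and ccl36.1 fell (-9.13, -9.11, -7.76 and -7.23), CPA1 by 5.17 without healthy sample 3. In all, 3896 genes changed, 1682 higher and 2214 lower. Library size alone gave 832 higher and 2366 lower and moved the median of all genes from -0.10 to -0.30. The count was 2036, 2173 and 1432 without hMYC samples 1, 2 and 3. Of 36 lists, 3 passed upwards and 15 downwards. By list, 14 of 28 immediate early and heat shock genes fell (14 adjusted over the list alone), such as FOSL1 (-4.05), and 9 of 21 antigen presentation genes fell (10 adjusted over the list alone), such as cd74a (-1.48). Further, 12 of 16 NK-like and cytotoxic genes fell (14 adjusted over the list alone) and 9 of 31 glycolysis genes fell (12 adjusted over the list alone), such as LDHA (-2.12) and PKM (-1.40). Here camera gave adjusted p = 1.71e-06, 0.000102, 0.000126 and 0.000126, and adjusted p = 0.612 for each with an estimated correlation. Of markers of other cells, 11 of 28 macrophage and dendritic genes fell (11 adjusted over the list alone), 11 of 27 fibroblast and matrix genes fell (21 adjusted over the list alone) and 11 of 19 skin genes fell (17 adjusted over the list alone). Testing by camera gave adjusted p = 4.12e-06, 9.02e-05 and 0.000232, and adjusted p = 0.612 for each with an estimated correlation. Fewer such cells and lower expression in thymocytes cannot be told apart here. Upwards, 8 of 77 cytosolic ribosomal protein genes rose (0 adjusted over the list alone) and 8 of 53 ribosome biogenesis genes rose and 1 fell (8 and 1 adjusted over the list alone). A camera test gave adjusted p = 6.71e-09 and 0.00165, and adjusted p = 0.612 and 0.631 with an estimated correlation.

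What changes between preleukemic thymocytes and leukaemia of a line was asked within the Frazer samples. In hulk, GAS8, a component of motile cilia, rose from 2.37 ± 1.06 CPM (SD, n = 3) to 26.3 ± 16.4 CPM (SD, n = 9), with log2 fold change 3.46 ± 0.59 (SE), edgeR adjusted p = 0.00539. Furthermore, CNIH1, ESD, SHD, the phosphatase gene ptp4a3a and the kinetochore gene ska1 rose by 2.90, 2.70, 2.64, 2.47 and 2.32 on the log2 scale. PKHD1L1, the cytokine gene il15, fbrsl1, PICK1, SLC26A11 and il12rb2l fell (-5.49, -3.52, -2.85, -2.73, -2.63 and -2.30), PICK1 with edgeR adjusted p = 0.000854. In all, 45 genes passed in hulk (18 higher, 27 lower). The split was 9 and 40 with DESeq2 size factors and 2 and 16 by library size alone, which moved the median of all genes from 0.14 to 0.01 and -0.22. The count was 105, 4 and 3 without preleukemic samples 1, 2 and 3, 71 without the libraries above 20% mitochondrial reads, 629 by the DESeq2 test and 1 with only these groups in the fit.

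In otg, liver and ribosomal protein genes rose, as did PLAC8L1, with log2 fold change 7.12 ± 1.92 (SE), edgeR adjusted p = 0.0137, and the oxidoreductase gene ERO1A, with 5.58 ± 1.19, edgeR adjusted p = 0.00349. Higher too were the prolyl hydroxylase genes P4HA2 and P4HA1, gra, FOXL2, the transferrin gene tfa, UCP1 and DESI1 (5.41, 4.23, 4.98, 4.96, 4.65, 4.48 and 4.03). ANKS1B, with -5.89 ± 0.72, edgeR adjusted p = 3.05e-06, ctsll, myhz2, hivep3b, plagl2, the kinase gene PRKCA, the oestrogen receptor gene ESR1 and tmprss4a fell (-5.25, -4.86, -4.80, -4.73, -4.26, -4.15 and -4.13). The totals in otg were 2636 genes, 1430 higher and 1206 lower. Scaling by library size alone gave 152 higher and 2432 lower and moved the median of all genes from -0.01 to -0.64. The total was 932, 1631, 1366 and 950 without preleukemic samples 1 to 4 in turn, and 169 with only these groups in the fit. By list, 10 of 16 liver genes rose (12 adjusted over the list alone) and 49 of 77 cytosolic ribosomal protein genes rose (65 adjusted over the list alone). Camera gave adjusted p = 2.62e-07 and 5.01e-26, and adjusted p = 0.342 for each with an estimated correlation. In shrek, DMGDH, opn4xb, SEMA4C, VSTM2A and SOBP had 0 reads in both preleukemic samples and were at least 780.1-fold, at least 514-fold, at least 379-fold, at least 321-fold and at least 285-fold higher. The collagen gene col5a3a rose with 9.86 ± 3.12, edgeR adjusted p = 0.0271. The interleukin receptor gene il20ra, with -8.11 ± 1.00, edgeR adjusted p = 1.55e-06, OSR2, rgs5b, myo1hb, ESR1, tgm1l2, ANKS1B and STMN4 fell (-7.80, -7.56, -7.54, -7.29, -7.17, -7.09 and -6.93). PCNA (-1.51) and LMO2 (-2.35) fell too. The totals in shrek were 3356 genes, 1336 higher and 2020 lower. The split was 1503 and 1470 with DESeq2 size factors. Leaving out either preleukemic sample lowered the total. Of S phase, 1 of 42 genes rose and 14 fell (1 and 17 adjusted over the list alone). Of macrophage and dendritic markers, 13 of 28 genes fell (20 adjusted over the list alone). The camera test gave adjusted p = 0.000452 and 1.38e-07, and adjusted p = 0.788 and 0.759 with an estimated correlation.

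**Figure D3:**
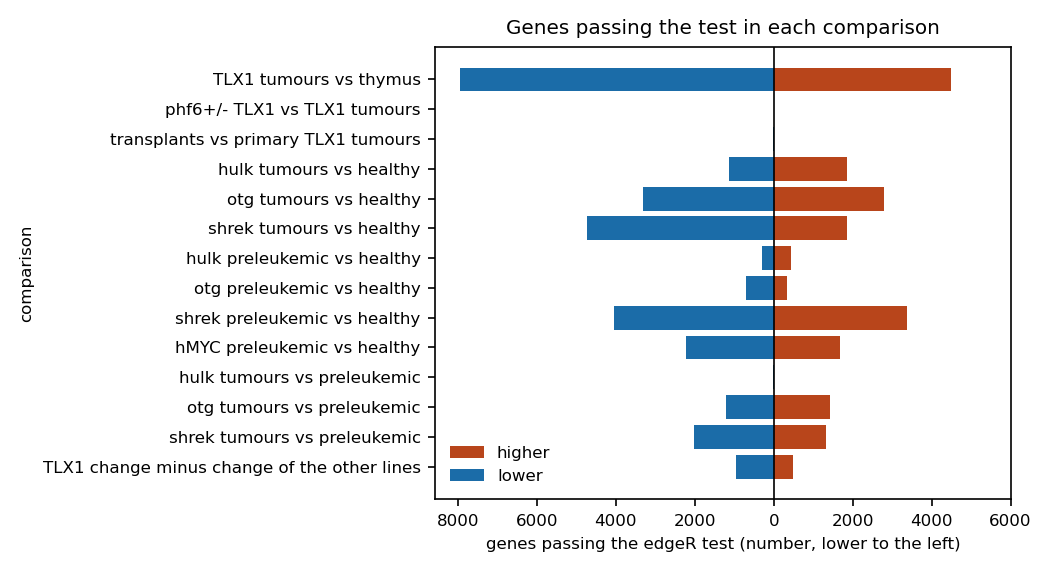
Number of genes higher (right) and lower (left) by the edgeR test in each comparison; the horizontal axis counts genes from 0. TLX1 tumours against thymus had the most, 12443, and the phf6 comparison of TLX1 tumours the fewest, 9.

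Whether the TLX1 model differs from the other leukaemia models was asked by the difference of their changes from healthy tissue, the primary TLX1 tumours against dissected thymi and the hulk, otg and shrek tumours against sorted thymocytes. The reference tissues differed, dissected thymus against sorted cells, and the laboratory moved with the model, so these cannot be told apart. The pancreatic enzyme genes CPB1 (log2 fold change 9.16 ± 1.68 (SE), edgeR adjusted p = 0.000987) and CELA1 (9.11 ± 1.73, edgeR adjusted p = 0.00133) were higher by this difference. So were ela2l, CEL, ctrb.3, amy2a and ela3l (8.77, 8.70, 8.69, 8.49 and 8.44). Healthy sample 3, above 20% mitochondrial reads, held 97.8% of the summed CPM of CPB1 and 93.8% of that of ela2l in healthy thymocytes. Without it the differences were 3.94 for CPB1, edgeR adjusted p = 0.0572, 5.42 for CELA1, 5.08 for ela2l, 3.85 for CEL, 3.75 for ctrb.3, 3.45 for amy2a and 3.54 for ela3l, and CPB1, CEL, amy2a and ela3l did not pass. The muscle genes mybpc2b (-11.70 ± 2.24, edgeR adjusted p = 0.00138) and MYBPC2, the cartilage genes MATN4 and COL11A2, ak7a and prkg1a (-9.23, -9.40, -9.17, -10.36 and -9.02) were lower. Of skeletal muscle markers, 15 of 29 genes fell (23 adjusted over the list alone). Here camera gave adjusted p = 2.05e-24, and adjusted p = 0.00136 with an estimated correlation. In all, 1439 of 22881 genes passed, 481 higher and 958 lower. Library size alone gave 208 higher and 3248 lower and moved the median of all genes from -0.19 to -1.03 (-0.35 with DESeq2 size factors). The count was 380 and 400 without TLX1 tumours 1 and 2, 888 without healthy sample 1 and 2643 by the DESeq2 test.

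Genes that change alike in the 4 leukaemia models were sought by overlap of calls among 20047 tested in all. SIM1, brinp2 and FOXL2 rose in each of TLX1, hulk, otg and shrek leukaemia, although hulk tumour 9 held 97.8% of the summed CPM of SIM1 in hulk tumours. Log2 changes were 6.37, 5.36, 6.05 and 6.95 for brinp2 and 5.42, 5.12, 5.86 and 6.49 for FOXL2. P4HA1 rose likewise (5.39, 6.18, 4.99 and 5.64). The thymic epithelium gene psmb11b, the enamel protein gene enam, myo1hb and TRPV6 fell in each, myo1hb by 7.34, 4.54, 4.76 and 8.16 and TRPV6 by 8.78, 4.04, 3.95 and 6.70 on the log2 scale. In all, 263 genes rose and 216 fell in the 4 models, 136 and 184 by at least 2-fold. Hulk, otg and shrek alone shared 369 and 377. The hulk, otg and shrek comparisons share their healthy libraries, which raises overlap without any effect. Shared calls were 812 higher and 546 lower for hulk and otg, 460 and 468 for hulk and shrek, and 1102 and 2493 for otg and shrek. Simulated unchanged groups, having few calls to share, shared 0. Independent lists would share 237.3 and 171.5, 157.9 and 245.5, and 238.9 and 716.1. With separate healthy libraries for each line they averaged 23.9 and 84.4, 15.3 and 79.7, and 122.8 and 956.4. Independent lists would then share 4.3 and 21.4, 2.7 and 39, and 16.7 and 240.4. Across genes, which are not independent replicates, the log2 fold changes had covariances of 1.73 (hulk and otg), 1.47 (hulk and shrek) and 2.93 (otg and shrek). Simulated shared controls alone gave 0.007, 0.006 and 0.005. Separate healthy libraries left 1.42, 1.12 and 2.46, so real shared libraries added more. TLX1 with hulk, otg and shrek gave 0.162, 1.68 and 2.12. TLX1 leukaemia, with controls of its own, shared 583 higher and 328 lower genes with hulk (313.7 and 339.8 by independent lists), 1605 and 1923 with otg (583.5 and 973.8) and 1041 and 2881 with shrek (377 and 1407.9).

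Levels of T-ALL genes in single leukaemias varied widely. In each of the 6 primary TLX1 tumours 1 MYC paralogue was high. There were 783 and 3.81 CPM of ENSDARG00000045695 in tumours 1 and 2, against 4.26 and 671 CPM of ENSDARG00000007241. Heterozygous tumours 1 to 4 had 510.4, 7.24, 256 and 557 CPM of the former and 7.11, 1064, 7.19 and 3.91 CPM of the latter. The interleukin-7 receptor gene il7r ranged over 22.7 to 1059 CPM in hulk, 92.5 to 887 in otg and 73.0 to 1439 in shrek tumours. The co-receptor gene cd8a ranged over 11.5 to 1736, 12.4 to 1139 and 59.2 to 728 CPM there. The thymic epithelium regulator foxn1 averaged 12.5 ± 1.7 CPM (SD, n = 6) in dissected thymi and had 3 reads over the 6 primary TLX1 tumours.

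**Figure D4:**
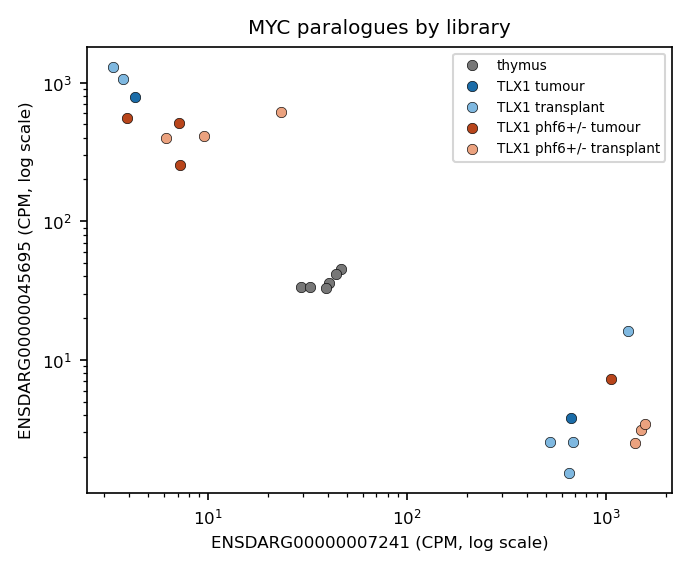
CPM of the MYC paralogues ENSDARG00000007241 (horizontal axis) and ENSDARG00000045695 (vertical axis), both on log scales, in thymi, primary TLX1 tumours and transplants; points are libraries. Thymi lay near equal levels, with log2 ratios of -0.18 to 0.24, and each primary tumour lay at a log2 ratio of at least 5.06 to one side or the other.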

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

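The tests of the MYC paralogues, of the muscle, skin and thymic epithelium markers, and of the fits by library size alone were chosen only after the result was seen, and that a median must pass its bound by its quartile was set after first values of 2 tests (all lower genes, gonad somatic cells). By a bound set before, a few genes taking most of the counts would have been excluded, and this was left open, and the splits of preleukemic hMYC judged too few, after all values were seen. After a first run, more random splits were drawn for preleukemic otg, the difference of models and all tests of hulk, otg and shrek tumours. Of 164 sets of 1 panel gene in 1 group of 4 to 10 samples, 20 held a sample far from the next one. Chance gives 1 in 20 only for Gaussian values in independent sets. MYC ENSDARG00000007241 was at 1064 CPM (others 3.91 to 7.19) in phf6 heterozygous TLX1 tumour 2, and MYC ENSDARG00000045695 at 3330.0 CPM (others 9.12 to 1226) in otg tumour 3. NOTCH1 ENSDARG00000052094 was at 877 CPM (others 0 to 34.2) and the terminal transferase gene dntt at 72.9 CPM (others 0 to 9.48) in the same shrek tumour, 007. NOTCH1 ENSDARG00000103554 was at 85.9 CPM (others 0 to 12.9) in otg tumour 9, and il7r at 1059 CPM (others 22.7 to 405) in hulk tumour 8 and 1439 CPM (others 73.0 to 782) in shrek tumour 006. The co-receptor gene cd8a was at 1736 CPM (others 11.5 to 377) in hulk tumour 7 and 1139 CPM (others 12.4 to 565) in otg tumour 8. PHF6 was at 20.2 CPM (others 13.6 to 15) and bcl2a at 2.31 CPM (others 11.5 to 13.9) in healthy thymocyte sample 3. NOTCH3 was at 39.1 CPM (others 20.1 to 26.9) in thymus 11 and lck at 650.4 CPM (others 936 to 979) in TLX1 transplant 1-1. Globin genes under the symbol HBE1 stood out in thymus, healthy thymocyte, otg tumour and preleukemic otg samples: ENSDARG00000069734 at 37.1 CPM (others 1.73 to 4.57) in the pooled thymus sample 2-3-5-6, ENSDARG00000097238 at 154 CPM (others 3.44 to 19.5) in healthy sample 1 and 66.2 CPM (others 0.0788 to 29.2) in otg tumour 8, and ENSDARG00000089087 at 337 CPM (others 9.94 to 41.2), 87.5 CPM (others 0 to 44.9) and, in preleukemic otg sample 2, 44.2 CPM (others 14.2 to 16.2). By a rule set after values were seen, 15 of 328 sets of a named gene in a group of at least 3 samples, with a mean of at least 8 CPM, had 80% or more of the summed CPM in 1 library. These were CPA1, HES1, hsp70.1, ela2l (in 2 comparisons), ela3l, amy2a, CEL, ctrb.3 and CPB1 in healthy sample 3, vtg1 and vtg7 in preleukemic hulk sample 3, SIM1 in hulk tumour 9, cacna1aa in hulk tumour 1 and fgf9 in preleukemic otg sample 3.

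The change of TLX1 tumours differed from that of the other lines, by the test of the difference itself, in CPB1 (9.16), CELA1 (9.11), ela2l (8.77), CEL (8.70), ctrb.3 (8.69), amy2a (8.49), ela3l (8.44), mybpc2b (-11.70), ak7a (-10.36), MATN4 (-9.40), MYBPC2 (-9.23), COL11A2 (-9.17) and prkg1a (-9.02), all log2 differences, the first 7 far smaller without healthy sample 3. Laboratory, reference tissue and model cannot be told apart for them. Among 40 splits of these samples the real one called 1439 genes and the highest other 3695, and 2 splits called at least as many as the real one, which is 5% or more, so chance cannot be excluded, and a split calling several times the real count points to a structure of the samples.

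A first pattern was the 7554 genes at least 2-fold lower in TLX1 tumours than in dissected thymi. A few genes taking most of the counts may lower values elsewhere, which stays open: 97.8% of these genes were still called lower without ribosomal protein genes and by library size alone, but on that scale the median of all genes was -0.94, so most stay lower whatever the cause. For 65 lower markers of muscle, skin and thymic epithelium, the median log2 ratio of sorted thymocytes to dissected thymi, less that of all genes, was -3.258 (quartiles -4.76 and -1.55), so other cells of the dissected tissue are a candidate source for them. Over all lower genes that median was -0.479 (quartiles -1.20 and 0.01), and 9.09% of them (687) were at least as high in sorted thymocytes at 5 CPM or more. Other cells and lower expression in tumour cells cannot be told apart for this wider set, since the quartiles span both and the sorted cells came from another laboratory.

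A second pattern was the germ-cell transcripts of hulk tumours, tested with 4 gene lists over 29 tumours. The 26 other germ-cell and meiosis genes moved with DDX4, DMC1 and PIWIL1, with medians of Spearman rho 0.817 (permutation p = 1e-05, adjusted 2e-05; within hulk, otg and shrek 0.916, 0.765 and 0.628) and Pearson r 0.931 (permutation p = 1e-05, adjusted 1.33e-05; 0.903 without the 2 farthest tumours), 1e-05 being the smallest p that 100000 permutations can give, and 18 spermatid genes likewise, with Spearman rho 0.817 (permutation p = 1e-05, adjusted 2e-05; within hulk, otg and shrek 0.842, 0.721 and 0.766) and Pearson r 0.932 (permutation p = 1e-05, adjusted 1.33e-05; 0.902 without the 2 farthest tumours). Gonad or leukaemic cells could each give this pattern (HORMAD1 up to 149 CPM, SYCP1 up to 101 CPM). Sorting for GFP should remove gonad cells, and healthy thymocytes expressed 4 and 2 genes of these lists at 1 CPM or more. For 6 genes of gonad somatic cells (3 expressed so) the medians were Spearman rho 0.549 (permutation p = 2e-05, adjusted 2.67e-05; within hulk, otg and shrek 0.667, 0.35 and 0.366) and Pearson r 0.629 (permutation p = 1e-05, adjusted 1.33e-05; 0.579 without the 2 farthest tumours), and for 2 oocyte genes Spearman rho 0.374 (permutation p = 0.00979, adjusted 0.00979; within hulk, otg and shrek 0.592, 0.036 and 0.316) and Pearson r 0.423 (permutation p = 0.00089, adjusted 0.00089; 0.426 without the 2 farthest tumours). Gonad cells and germ-cell genes switched on in leukaemic cells cannot be told apart by 0.549, because few somatic genes were measured and their first quartile was 0.308.

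Another pattern was the single high MYC paralogue of each TLX1 tumour, seen in some hulk, otg and shrek tumours too. Hulk tumour 7, for example, had 815 CPM of ENSDARG00000045695 and 32.2 CPM of ENSDARG00000007241. Reads shared between paralogues would hold both IDs near 1 ratio, but the SD of their log2 ratio was 7.049 over the 6 primary tumours, against 0.153 in thymi. A trait of each tumour that its transplants keep is a candidate explanation. All 12 transplant libraries from 4 tumours, 2 of them passed on, had the same paralogue ahead as the tumour of origin. Nothing in the labels gives a biological cause to test.

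Regrouping the same samples tested whether chance gives as many genes. Chance can be excluded, as fewer than 5% of splits called as many, with the real count and the highest of the other splits, for TLX1 tumours (12443 against 1412), hulk (2983 against 631), otg (6105 against 4186) and shrek tumours (6593 against 1928), the 3 lines (11730 against 4432), preleukemic otg (1041 against 1941, 2 of 100 splits) and otg tumours against preleukemic (2636 against 553), where the real split was 1 of its splits except as given. For preleukemic hMYC (3896 against 3402), whose numbers pair samples, the 7 other splits parting 3 pairs called at most 3402 genes, those parting 2 at most 1352, and those parting 1 or 0 at most 1 and 0, and the splits parting 3 pairs are too few for a share under 0.05. Chance cannot be excluded for preleukemic hulk (737 against 4215, 3 of 56 splits) or hulk tumours against preleukemic (45 against 217, 3 of 40), and splits calling several times the real count point to a structure of the samples. The 8 splits of transplants against primary tumours are too few for a share under 0.05 (19 genes, highest other 0).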

How the results depend on the processing

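Fits by library size alone, without mitochondrial genes, without libraries above 20% mitochondrial reads or with fewer than 12000 genes, and without marker genes or the transplants passed on from another were chosen only after the data were seen, and the others before. The 326 named gene results were refitted 4777 times in all. Of the values of genes called higher, 2027 kept direction and call and 189 kept direction and missed the threshold, and of those of genes called lower 2347 and 186, and no such value changed sign. Of genes not called, 5 values passed, and the direction of PHF6 in the phf6 comparison and of MYC ENSDARG00000007241 in TLX1 tumours reversed, PHF6 to 0.68 (the other leave-outs down to -0.92) without TLX1 tumour 1 and 0.01 with a replicate block, and MYC to -0.18 (the others up to 3.49) without TLX1 tumour 2 and -0.72 by limma voom. Without TLX1 tumour 1 the PHF6 comparison rests on tumour 2, low in PHF6, and for the other reversals the cause was not tested.

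Of the counts of genes passing the test, 97 values under alternatives stayed within 1.5 times the main count, 26 were higher and 20 lower. The main counts of those that moved were 9 for the phf6 comparison, 19 for transplants, 2983 for hulk tumours, 6105 for otg tumours, 6593 for shrek tumours, 11730 for the 3 lines, 737 for preleukemic hulk, 1041 for preleukemic otg, 7424 for preleukemic shrek, 3896 for preleukemic hMYC, 45 for hulk tumours against preleukemic, 2636 for otg tumours against preleukemic, 3356 for shrek tumours against preleukemic and 1439 for the difference of models. By the DESeq2 test the counts were 707 for the phf6 comparison, 666 for transplants, 1883 for preleukemic hulk, 2058 for preleukemic otg, 629 for hulk tumours against preleukemic and 2643 for the difference of models. By limma voom they were 1 for the phf6 comparison, 7174 for hulk tumours, 11348 for shrek tumours, 1415 for preleukemic hulk, 4912 for preleukemic otg, 8581 for preleukemic hMYC, 1102 for hulk tumours against preleukemic, 7184 for otg tumours against preleukemic, 8339 for shrek tumours against preleukemic and 7252 for the difference of models. By library size alone they were 301 for transplants, 424 for preleukemic hulk, 18 for hulk tumours against preleukemic, 1901 for shrek tumours against preleukemic and 3456 for the difference of models, and with no filter on low counts 14 for the phf6 comparison, 211 for transplants and 25 for hulk tumours against preleukemic. With only the compared groups in the fit, and so fewer samples, they were 1769 for otg tumours, 105 for preleukemic hulk, 1 for hulk tumours against preleukemic and 169 for otg tumours against preleukemic. With a replicate block, for which only the hMYC numbers met the pairing rule, they were 0 for the phf6 comparison, 1575 for hulk tumours, 864 for otg tumours, 3887 for shrek tumours, 3408 for the 3 lines, 36 for preleukemic hulk, 253 for hulk tumours against preleukemic, 437 for otg tumours against preleukemic and 1896 for shrek tumours against preleukemic. In preleukemic hMYC the paired fit changed the call of no named gene, and of 13 of 36 lists, none of them described for hMYC. Without libraries above 20% mitochondrial reads they were 1948 for hulk tumours, 2181 for preleukemic hulk and 71 for hulk tumours against preleukemic, and without those with fewer than 12000 genes 365 for hulk tumours against preleukemic. For transplants, each library on its own gave 336, no replicate block 0 and the count without the 2 libraries passed on from transplant 2-2 was 14 by edgeR. Beside the edgeR counts of 0, 198 genes of the phf6 comparison with a block and 766 of transplants without one had an unadjusted p under 0.05, and other tools were not run on those models. With the correlation estimated per list, 1 list test passed in place of 218. Beyond fewer samples in a fit and more variance removed or kept by a block, the cause was not tested.

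Leaving out 1 sample at a time, 41 counts stayed within 1.5 times the main count, 9 were higher and 29 lower. The ranges were 11583 to 13475 for TLX1 tumours, 8 to 155 for the phf6 comparison, 7 to 52 for transplants, 1384 to 3065 for hulk tumours, 4671 to 5504 for otg tumours, 4842 to 6374 for shrek tumours, 203 to 4441 for preleukemic hulk, 372 to 1851 for preleukemic otg, 2987 to 7879 for preleukemic shrek, 1432 to 4941 for preleukemic hMYC, 3 to 105 for hulk tumours against preleukemic, 932 to 1631 for otg tumours against preleukemic, 772 to 803 for shrek tumours against preleukemic and 380 to 1656 for the difference of models. A sample left alone in its group was assumed to vary like the other groups. All 4 models shared 479 called genes (263 up), 320 at 2-fold or more (136 up). Depth limited genes with few reads, which were filtered. Simulated 2-fold recovery was at most 15 of 100 with few genes changed, which may understate tests calling many.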

Other observations

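The test of a hypoxia list was set down before its values were seen, after P4HA1, ANKRD37 and ERO1A had been seen to rise in tumours, ERO1A without passing in shrek. A wider hypoxia-type response might raise these genes. The other genes of a hypoxia list had median log2 fold changes of -0.23, 0.71, 0.10 and -1.60 in TLX1, hulk, otg and shrek tumours. Of 29, 28, 28 and 28 genes of that list, 5, 1, 5 and 3 rose and 6, 0, 4 and 12 fell (4, 0, 5 and 3 and 6, 0, 4 and 13 adjusted over the list alone), with camera adjusted p = 0.676, 0.23, 0.676 and 0.232, and adjusted p = 0.857, 0.622, 0.857 and 0.622 with an estimated correlation. No rise of the whole list was shared by the 4 models, and a narrower response was not tested.

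Mitochondrial transcripts took 22% of reads in healthy thymocyte sample 3, 15.7% in preleukemic hulk sample 3 and 11.9% in otg tumour 5, beside the hulk tumours given above.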
